A study of Mus musculus with 4 samples.

How the data were processed

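The series holds 4 droplet single-cell RNA libraries from the dorsal skin of C57BL/6J mice at postnatal day 3, from which melanocytes were enriched by fluorescence-activated sorting, per the labels. The markers of the sorting gate and the number of mice per library are not given in the sources used here. Libraries were prepared with a 10x Genomics Chromium 3′ kit, per the labels' protocols. The 4 groups held 1 library each and formed 2 pairs, in which a yellow library was harvested and sequenced beside its own nonagouti library, per the series design. The pairing was taken from the titles.

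The deposited values were counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger, per the submitters' processing notes, and not normalized. The submitters' notes also name Partek and the build mm39, and the header of the second matrix of each library names Cell Ranger 4. The reference at hand was another build (GRCm38), so no coordinates are given. Genes carry the symbols and Ensembl identifiers of the deposited files, and the reference was used only to find the chromosome of a few genes by identifier. Each library had 2 unfiltered matrices. The matrices with 32285 features in all 4 libraries were used. The second matrices of the recessive yellow pair were identical to the first, and those of the lethal yellow pair had 31053 features and served as an alternative.

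A barcode was taken as a cell with at least 1000 UMIs and at least the 99th percentile of the 3000 largest barcodes divided by 10, at least 500 genes, and at most 10% mitochondrial UMIs. The resulting minimum was 3195 UMIs in lethal yellow, 3515 in its nonagouti library, 6960 in recessive yellow and 5080 in its nonagouti library. Scrublet, as in scanpy 1.11.5, marked 31, 42, 5 and 65 doublets in these libraries, which were removed. The 5 doublets among 1531 cells of recessive yellow, or 0.327%, were a low yield, so doublets may remain there. Cells were log-normalised, and 2000 variable genes were chosen without pigment, mitochondrial, ribosomal, haemoglobin, X inactivation and Y genes. They were standardised within each library, reduced to 30 principal components and clustered with leidenalg 0.10.2 at resolution 0.3 with 15 neighbours. A first clustering without standardisation within libraries parted cells by pair, and the standardisation and the resolution were set after that was seen. Clusters were named from 18 marker lists, and a class name ends in "-like" because it rests on these markers.

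UMIs were summed per library over melanocyte-like cells. With 1 library per genotype there was no replicate check within a pair, and cells were not used as replicates. Ratios of CPM (UMI counts scaled to the same total in each library) are given on the log2 scale, yellow over nonagouti, with exact conditional binomial 95% intervals that cover counting error only. Against a library with no UMIs of a gene, the ratio was taken against a floor of 3 counts in that library. Genes with at least 50 UMIs over a pair entered the comparisons. For each of 19 gene lists the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The lists cover the allele check, melanin enzymes and melanosome proteins, melanosome biogenesis and transport, cysteine and glutathione metabolism, MC1R and cAMP signalling, melanocyte lineage factors, T-box factors with reported targets, neural crest and immature melanoblast genes, WNT targets, cadherins and adhesion, NRF2 targets, S phase, G2 and M phase, dissociation and immediate early genes, unfolded protein response, interferon response, glycolysis, nuclear oxidative phosphorylation genes, and X inactivation and Y genes.

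The difference shared by both yellow genotypes was tested on the counts with edgeR 4.0.16, using the quasi-likelihood test with pair as a block, TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. This fit had 1 residual degree of freedom, so a gene's own error is the difference between the 2 pairs' effects plus the noise between libraries. The quasi-likelihood fit draws this error toward that of the other genes. Its p-values and SEs thus rest largely on the spread over all genes tested, not on a gene's own counts alone. Nothing says that the animals of a pair were more than 1 each, so p-values measure only the spread between these libraries. DESeq2 1.42.0 was an alternative. Counts of 11625 genes were simulated with the same dispersion, 0.0195, for all genes. In these the fit recovered 60 of 100 genes changed 2-fold and 96 of 100 changed 4-fold, with 6 false calls. In pairs of 9190 genes simulated with counting error alone, the 95% intervals held the true ratio in 94% to 99% of genes. Unchanged genes there had median absolute log2 ratios of 0.07 and 0.12, against 0.20 and 0.26 over the genes of the real pairs. The simulated pairs thus do not test coverage under the spread between real libraries.

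Cycling cells were those with UMIs of at least 2 genes of the G2 and M phase list after thinning to 2000 UMIs per cell. The alternative of cells outside G2 and M phase used the same rule without thinning, so it left out more cells and depends on depth. It left out 538 of 1216 melanocyte-like cells of lethal yellow and 278 of 643 of its littermate. In the recessive pair it left out 52 of 113 and 170 of 318. Shares of cells with a UMI of a gene were taken after thinning to 3000 UMIs, and shares carry exact binomial intervals. Beside a share of 0, the limit printed is that of 3 cells, which lies below the exact upper bound. For Tbx3 in 0 of 318 control cells of the recessive pair, the limit is 0.943% and the exact bound 1.15%.

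The samples, tests, lists, markers, alternatives and the rule for named genes were fixed before the data were examined. The rule named the allele check genes, Tbx3 and Mc1r, then per pair the 10 genes higher and the 10 lower whose interval bound nearest to no difference was largest, then 12 genes in each direction with the largest smaller bound of both pairs. It also named up to 4 members of each list and up to 2 markers per other cell type. Mitochondrial, ribosomal, haemoglobin, X inactivation, Y and unnamed genes and markers of other cell types were left out of the parts by size. These were Cma1 and Cpa3 in the lethal pair, Dcn, C1qa and C1qb in the recessive pair, and Gm10639 and Gm45895 over both pairs. The rule gave 140 genes, of which 4 are not reported here one by one and are left out of the counts of named genes under alternatives. The alternatives changed the UMI minimum, mitochondrial limit, doublets, matrix, clustering, choice of cells, weight of cells, scaling, count minimum, pseudocount, block, tool and filter. Added after the data were seen were leaving out cells with over 0.25% of their UMIs in markers of other cell types, leaving out each gene's top cell, the share of cells with 2 of 5 lineage genes, and the median over the 10 named genes as the summary of a pair. A limit of 0.5% was tried first and removed few cells, and it was lowered before any result under it was looked at. The markers counted for this limit left out those of Schwann cells, neurons and Merkel cells.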

Results

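Melanocytes make eumelanin, a black or brown pigment, when the receptor MC1R signals, and pheomelanin, a yellow pigment, when it does not. The series compared skin cells of 2 kinds of yellow mice with black nonagouti controls. Lethal yellow mice express agouti, an antagonist of MC1R, in all tissues, and recessive yellow mice carry an inactive form of MC1R. Total counts were 45828017 UMIs in lethal yellow, 44274926 in its nonagouti littermate, 45592381 in recessive yellow and 53002661 in its nonagouti control. These libraries held 3511, 2535, 1526 and 2393 cells, with medians of 9611, 12148, 26408 and 17927 UMIs per cell. Each group was 1 library, so differences within a pair had no replicate check, and all intervals cover counting error only.

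Agouti (symbol a, ENSMUSG00000027596) gave 2601 UMIs in the melanocyte-like cells of lethal yellow and 0 in those of its littermate, at least 526-fold higher against a floor of 3 counts. In the recessive pair it gave 39 and 72 UMIs, a log2 ratio of 0.26 (95% interval -0.34 to 0.84). The 2 nonagouti libraries thus differed in agouti. After thinning to 3000 UMIs, 2.83% of melanocyte-like cells of the recessive control held an agouti UMI, against 0 of 643 in the littermate of lethal yellow. Its 13.5 CPM in that control lay below the 24.5 CPM of barcodes of at most 100 UMIs, so free RNA stays open there. Raly and its neighbour Eif2s2, which lie in the stretch deleted in the lethal yellow allele, had log2 ratios of -0.95 (-1.07 to -0.83) and -0.66 (-0.72 to -0.59) in the lethal pair. In the recessive pair they had -0.09 (-0.25 to 0.07) and 0.25 (0.14 to 0.36). Ahcy, a further gene of this region, had -1.07 (-1.58 to -0.56) in the lethal pair and 0.14 (-0.76 to 1.00) in the recessive pair. Mc1r (ENSMUSG00000074037) was higher in both yellow libraries, at 508 against 152 CPM in the lethal pair and 478 against 114 CPM in the recessive pair. The level of a 3′ tag does not read the recessive yellow variant, so the genotype of that library was not checked by its counts. The median over the 5 genes was -0.66 in the lethal pair and 0.25 in the recessive pair, and in the shared fit 1 rose and 0 fell over all genes tested, or 2 rose and 1 fell adjusted over the list alone.

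Melanocyte-like cells, led by Dct, Pmel, Mlana, Ptgds and Tyr, made up 34.6% of cells (33.1 to 36.2) in lethal yellow and 25.4% (23.7 to 27.1) in its littermate. In recessive yellow they made up 7.40% (6.14 to 8.84), or 113 cells, against 13.3% (11.95 to 14.7), or 318 cells, in its control. The share was thus higher in 1 yellow library and lower in the other, and the sorting gate can set such shares. Cells with UMIs of at least 2 of 5 lineage genes, from any cluster, were 43.7% (42.1 to 45.4) and 34.9% (33.1 to 36.8) in the lethal pair and 24.6% (22.5 to 26.9) and 23.9% (22.2 to 25.6) in the recessive pair, so the lower recessive share was not found by that choice. Only 112 of these 376 cells in recessive yellow and 316 of 571 in its control were melanocyte-like. That choice thus counts many other cells and does not settle the melanocyte-like share. Hair follicle epithelium-like cells, led by Krt35, Krt28 and Krt71, took 64.5% of recessive yellow cells (62.1 to 67.0) and 35.8% (33.9 to 37.8) of its control, against 17.5% and 16.9% in the lethal pair. Different clusters held this class in the recessive pair, with 3, 827 and 155 cells of recessive yellow in clusters 1, 3 and 7 and 624, 90 and 143 of its control, so values within it compare different cells. Basal keratinocyte-like cells were 10.8% and 19.5% in the lethal pair and 8.98% and 17.97% in the recessive pair. Fibroblast-like, endothelial-like, Schwann cell-like and dermal papilla-like cells were found in all 4 libraries. Unnamed cells took 10.0%, 9.63%, 3.34% and 11.4% of lethal yellow, its littermate, recessive yellow and its control. Clusters 0 and 12 held the melanocyte-like cells of the lethal pair, where genes of cell division such as Prc1, Cenpa and Ccnb2 led cluster 12, and cluster 8 held most of those of the recessive pair. The melanocyte-like sums were 12490007, 7577731, 2415981 and 5341901 UMIs.

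**Figure D1:**
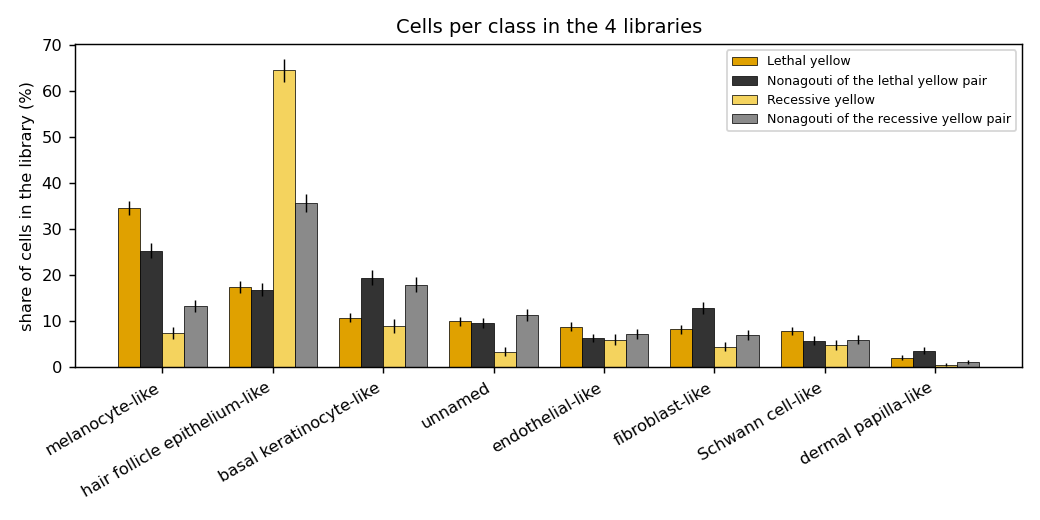
Bars give the share of each library's cells (%) in each class, with exact binomial 95% intervals that cover counting error only, for 1 library per group. Melanocyte-like cells were 34.6% and 25.4% in the lethal yellow pair and 7.40% and 13.3% in the recessive yellow pair.

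The lethal yellow pair asked what constant agouti does to melanocytes against a littermate without it. Besides agouti, the genes with the largest differences higher in the lethal yellow library included Rasgrp3, an activator of Ras, at a log2 ratio of 6.68 (5.12 to 8.96), and Lmo2, a LIM domain transcriptional regulator, at 4.33 (3.87 to 4.84). The collagen gene Col14a1 had 4.25 (3.87 to 4.64), Akap12, a scaffold of protein kinase A, 5.55 (3.67 to 8.60), and the progesterone receptor gene Pgr was at least 21.8-fold higher, with 108 against 0 UMIs. Cst7, an inhibitor of cathepsins, had 5.94 (3.43 to 11.26), Tmsb15a 5.82 (3.30 to 11.14), Luzp2 5.77 (3.26 to 11.09) and the serine protease gene Prss23 3.79 (3.04 to 4.64). Lower in the lethal yellow library were the carbonic anhydrase gene Car4 at -7.32 (-9.61 to -5.76), the activin receptor gene Acvr1c at -7.22 (-8.67 to -6.08) and Tyrp1, an enzyme of eumelanin synthesis, at -3.97 (-4.07 to -3.87). S100b had -5.12 (-6.36 to -4.11), Dbpht2 -5.36 (-7.01 to -4.10), the heparan sulfotransferase gene Hs3st1 -5.09 (-5.98 to -4.32), the kinase gene Pak3 -4.95 (-6.03 to -4.03) and D7Ertd443e -4.49 (-5.03 to -3.99). The peptide transporter gene Slc15a2, with 0 against 72 UMIs, was at least 39.6-fold lower, and the cAMP phosphodiesterase gene Pde7b, with 0 against 57, at least 31.3-fold lower. The median of the 10 named higher genes was 5.66 and of the 10 named lower genes -5.11, both inflated because these genes were picked for their size. In the pair, 10505 genes had at least 50 UMIs, with a median absolute log2 ratio of 0.20. With 1 library each, no test of the genotype was possible.

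The recessive yellow pair asked the same of melanocytes whose receptor is inactive. Higher in the recessive yellow library were Rasgrp3 at a log2 ratio of 6.00 (4.85 to 7.47), the glutamate receptor gene Grm8 at 4.82 (4.18 to 5.54), Akap12 at 4.14 (3.52 to 4.81), Col14a1 at 4.10 (3.64 to 4.59), the chemokine gene Cxcl14 at 4.01 (3.55 to 4.50) and Pgr at 5.23 (3.60 to 7.56). Lower were Tyrp1 at -5.11 (-5.45 to -4.79), Pde7b at -5.64 (-7.09 to -4.51), Acvr1c at -5.62 (-7.50 to -4.25), Car4 at -5.92 (-11.24 to -3.42), D7Ertd443e at -4.45 (-5.37 to -3.66) and Thsd7a at -3.96 (-4.78 to -3.25). The glutamate receptor gene Grin2b, with 0 against 94 UMIs, was at least 14.2-fold lower. Several of the genes named by size rested on single cells among the 113 and 318. In recessive yellow, 1 cell held 861 of 862 UMIs of Ccer2, 37 of 54 of Tmtc1, 28 of 53 of Rassf9 and 36 of 97 of Ptn. In its control, 1 cell held 92 of 92 UMIs of Actc1, 109 of 109 of Ccl4 and 68 of 78 of Ctss. The medians of the 10 named genes were 5.03 and -4.24, inflated as in the lethal pair, over 9419 genes with at least 50 UMIs and a median absolute log2 ratio of 0.26. Without each gene's top cell these medians were 4.52 and -5.11.

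Many genes differed in the same direction in both pairs. Of 9190 genes measured in both, 124 were at least 2-fold higher and 135 at least 2-fold lower in both yellow libraries, while 6 went 2-fold in opposite directions. Rasgrp3, Col14a1, Pgr, Akap12, Grm8, Prss23, Cort, Lmo2, Epha3, Luzp2 and Slc7a11 stood out among those higher in both, and Acvr1c, Car4, Pde7b, Tyrp1, D7Ertd443e, Mme, Lama3, Olfml1, Adam33, Gsta2 and Plagl1 among those lower in both. The neuropeptide gene Cort had log2 ratios of 3.48 (2.88 to 4.15) and 4.22 (3.09 to 5.60) in the lethal and recessive pairs, and the ephrin receptor gene Epha3 had 3.87 (2.72 to 5.34) and 3.19 (2.61 to 3.82). The glutathione transferase gene Gsta2 had -3.85 (-4.35 to -3.39) and -3.27 (-4.29 to -2.41), the peptidase gene Mme -3.65 (-4.26 to -3.09) and -4.70 (-6.99 to -3.13), and Plagl1 -2.75 (-3.02 to -2.50) and -3.13 (-3.79 to -2.54). Across genes, which are not independent replicates, the log2 ratios of the pairs had a Pearson r of 0.60 and a Spearman rho of 0.38. In the 5 other named classes with enough cells r lay between 0.00096 and 0.154, with 2 to 16 genes in the same direction and 3 to 9 in opposite ones. The 0.154 is that of hair follicle epithelium-like cells, mostly of cluster 3 in recessive yellow and cluster 1 in its control, and the next was 0.123, in endothelial-like cells. No library was shared by the pairs. With cells taken by UMIs of at least 2 of 5 lineage genes from any cluster, 32 genes were higher and 181 lower in both, 40 went in opposite directions and r was 0.27, and of the 259 genes above only 99 stayed at 2-fold in both. In recessive yellow only 112 of those 376 cells were melanocyte-like, and 31 ratios of named genes turned direction, among them those of Prss23, Luzp2, Lama3, Mlana and Nes in the recessive pair and of Sparc in both.

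**Figure D2:**
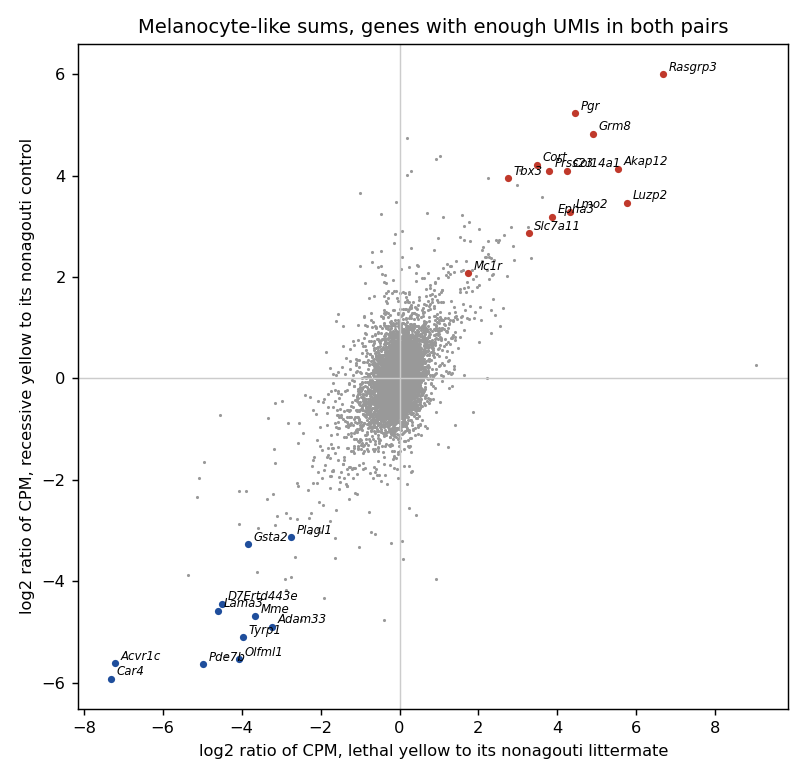
Each grey point is 1 of 9190 genes, placed by its log2 ratio of CPM in the lethal yellow pair (x axis) and in the recessive yellow pair (y axis), over melanocyte-like sums. Red and blue points are the genes named as higher or lower in both pairs, with Tbx3 and Mc1r, and ratios against 0 UMIs are drawn at the floor of 3 counts. The lone point at the right is agouti, at 9.04 and 0.26.

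Tbx3 (ENSMUSG00000018604), the T-box transcription factor named in the series title, was higher in both yellow libraries. It gave 452 against 41 UMIs in the lethal pair, 36.2 against 5.41 CPM and a log2 ratio of 2.74 (2.28 to 3.24). In the recessive pair it gave 112 against 16 UMIs, 46.4 against 3.00 CPM and 3.95 (3.19 to 4.81). After thinning to 3000 UMIs, 10.6% of lethal yellow (8.93 to 12.5) and 2.18% of littermate melanocyte-like cells (1.20 to 3.63) held a Tbx3 UMI, and 7.96% (3.71 to 14.6) against 0 of 318 cells in the recessive pair, which allows up to 0.943% of thinned cells with a UMI and sets no limit on cells that express the gene. Unthinned shares were 25.7%, 5.75%, 46.9% and 3.46%, at median depths of 8911, 9944, 16260 and 15847 UMIs. In endothelial-like cells the thinned shares were 5.79%, 3.11%, 2.20% and 2.30%, at medians of 6987, 8307, 16098 and 10517 UMIs, and in basal keratinocyte-like cells of the lethal pair 0.264% and 0 of 495, which allows up to 0.606%. Barcodes of at most 100 UMIs held Tbx3 at 8.54, 1.02, 1.27 and 0.75 CPM in lethal yellow, its littermate, recessive yellow and its control. A low level of Tbx3 in nonagouti melanocyte-like cells is thus not excluded. The list of T-box factors and reported targets, which holds Tbx3 itself, had medians of 0.40 and 0.48 over 5 measured genes, at percentiles 99.7 and 98.5 of random lists. In each pair 3 of these genes were higher and 2 lower, and both medians are the value of Cdh1 alone. The list gives no direction for its targets, so the percentiles do not read the action of TBX3 on them. With cells taken by 2 of 5 lineage genes the recessive median turned to -0.39. Among its members, Cdkn1a, the gene of the cell cycle inhibitor p21, had 0.97 (0.72 to 1.22) and 2.78 (2.45 to 3.11), and the E-cadherin gene Cdh1 0.40 (0.28 to 0.51) and 0.48 (0.27 to 0.69), the latter -0.40 by that choice of cells. In the shared fit 2 of the 5 rose and 0 fell, or 3 and 0 adjusted over the list alone.

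**Figure D3:**
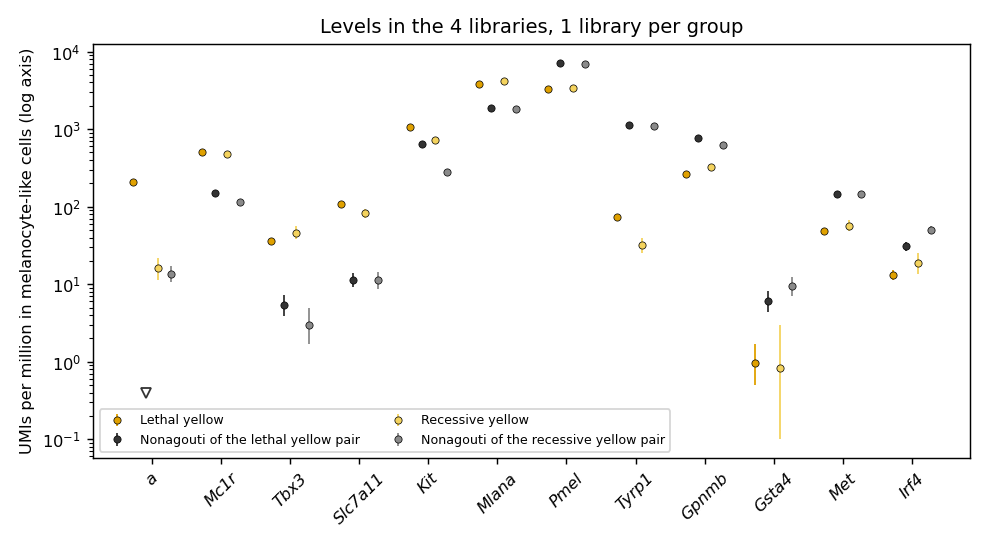
Points give CPM (log axis) of 12 genes in the melanocyte-like sums of the 4 libraries, 1 per group, with exact Poisson 95% intervals that cover counting error only. The open triangle marks the floor of 3 counts for agouti in the littermate of lethal yellow, which had 0 UMIs. Tbx3 stood at 36.2 and 46.4 CPM in the yellow libraries and at 5.41 and 3.00 CPM in the nonagouti ones.

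The test over all 4 libraries, with pair as a block, asked which genes moved alike in both yellow genotypes. Rasgrp3 rose by a fitted log2 of 6.24 ± 0.29 (SE), Col14a1 by 4.18 ± 0.19 and Slc7a11 by 3.09 ± 0.19. Tyrp1 fell by 4.44 ± 0.24 and Acvr1c fell by 6.66 ± 0.31. Tbx3 rose by 3.22 ± 0.27, with an adjusted p of 2.4e-05 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and was higher in 2 of 2 pairs. By the same edgeR test and Benjamini-Hochberg adjustment, the p was 3.3e-07 for Rasgrp3, Col14a1 and Acvr1c, 1.6e-06 for Tyrp1 and 3.1e-06 for Slc7a11. Of 11887 genes tested, 343 rose and 366 fell. The fit has 1 residual degree of freedom, and without the pair block 0 genes passed in either direction with edgeR, against 276 and 277 at an unadjusted p under 0.05 and 56 and 66 with DESeq2. DESeq2 with the block called 134 and 150 genes, and with cells taken by 2 of 5 lineage genes edgeR called 0 and 1, against 256 and 727 unadjusted and 23 and 111 with DESeq2. A mitochondrial limit of 20% gave 209 and 228 with edgeR.

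Pigment genes did not all go the same way. Tyrp1 stood at 72.9 against 1143 CPM in the lethal pair and at 31.9 against 1101 CPM in the recessive pair, and Pmel, the fibril protein of the melanosome, fell with log2 ratios of -1.10 (-1.11 to -1.08) and -1.03 (-1.06 to -0.99). Gpnmb also fell, at -1.55 (-1.61 to -1.49) and -0.97 (-1.09 to -0.86), while Mlana rose, at 1.06 (1.03 to 1.08) and 1.18 (1.14 to 1.22), the latter -0.039 with cells taken by 2 of 5 lineage genes. A Tyrp1 UMI was found in 8.31% of thinned lethal yellow cells against 81.8% in the littermate, and in 2.65% against 78.0% in the recessive pair. The unthinned shares were 13.7%, 91.9%, 11.5% and 90.3%, and endothelial-like cells had 0.322%, 3.11%, 0 of 91 and 0 of 174 when thinned, where the last 2 allow up to 3.30% and 1.72%. Over the list of melanin enzymes and melanosome proteins the medians were -0.14, at percentile 1.04, and -0.11, at percentile 13.9. In the fit 2 of 18 rose and 5 fell, or 3 and 7 adjusted over the list alone. Of melanosome transport genes, Rab27a fell, with -1.03 (-1.15 to -0.91) and -0.83 (-1.10 to -0.56), and Myo5a fell, with -0.71 (-0.80 to -0.62) and -0.49 (-0.63 to -0.35), while Rab38 rose, with 0.77 (0.59 to 0.96) and 0.71 (0.49 to 0.93). Mlph, which links RAB27A to myosin 5A, had 0.49 (0.35 to 0.62) and 0.58 (0.38 to 0.79) and did not pass. By 2 of 5 lineage genes the recessive ratios turned to -0.42 for Rab38 and -0.63 for Mlph. The list of melanosome biogenesis and transport had medians of -0.18 over 26 genes and 0.0044 over 24, the latter -0.042 under TMM scaling, and 1 rose and 5 fell, or 3 and 5 adjusted over the list alone.

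Slc7a11, a subunit of the exchanger that brings cystine into the cell, was higher in both yellow libraries, with log2 ratios of 3.27 (2.96 to 3.61) and 2.87 (2.44 to 3.31). In the nonagouti libraries 1 cell each held 36 of 86 and 27 of 60 of its UMIs. Of the cysteine and glutathione list, Gstm1 rose, with 0.87 (0.72 to 1.03) and 0.98 (0.74 to 1.22), and Gsta4 and Mgst1 fell, with -2.66 (-3.71 to -1.72) and -3.53 (-6.61 to -1.60), and -0.81 (-0.93 to -0.70) and -1.06 (-1.29 to -0.83). The list's medians were 0.14, at percentile 89.4, and 0.23, at percentile 98.5. In the fit 2 of 18 rose and 2 fell, with the same counts adjusted over the list alone. Among NRF2 targets Txnrd1 rose, with 0.65 (0.52 to 0.78) and 1.07 (0.87 to 1.26), while Prdx6 had 0.51 (0.36 to 0.65) and 0.42 (0.22 to 0.63) and Fth1 0.25 in both pairs without passing. The recessive ratios turned to -0.22 for Gstm1 and -0.21 for Fth1 with cells taken by 2 of 5 lineage genes, and to -0.022 for Prdx6 in cells outside G2 and M phase. The medians were 0.16, at percentile 93.7, and 0.28, at percentile 99.6 (-0.047 with cells taken by 2 of 5 lineage genes), and 2 of 16 rose and 0 fell, or 4 and 0 adjusted over the list alone. Slc7a11 is in both lists.

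Within the receptor's own pathway, Mc1r rose, with log2 ratios of 1.74 (1.65 to 1.83) and 2.07 (1.93 to 2.22), and the phosphodiesterase genes Pde4b and Pde3a fell. Pde4b had -2.60 (-3.10 to -2.12) and -2.78 (-3.44 to -2.18), and Pde3a -2.12 (-2.47 to -1.77) and -0.69 (-0.96 to -0.44). Nr4a2, a nuclear receptor induced by cAMP, rose, with 1.10 (0.82 to 1.38) and 3.18 (2.95 to 3.43). The MC1R and cAMP list had medians of -0.12, at percentile 4.55, and 0.30, at percentile 99.98 (-0.15 with cells taken by 2 of 5 lineage genes), and 3 of 27 rose and 3 fell, or 4 and 4 adjusted over the list alone. In the 5 other classes its lethal medians ran from -0.20 to -0.067, so the -0.12 is not particular to melanocyte-like cells. Its recessive medians there ran from -0.44 to 0.048. Of lineage genes the growth factor receptor gene Kit rose, with 0.72 (0.67 to 0.76) and 1.35 (1.25 to 1.45), and the WNT effector gene Lef1 rose, with 1.26 (1.00 to 1.52) and 1.07 (0.82 to 1.33). In cells outside G2 and M phase the recessive ratio of Lef1 turned to -0.049, and its 106 and 50.4 CPM in that pair lay below the 205 and 114 CPM of barcodes of at most 100 UMIs in the same libraries. The transcription factor gene Irf4 fell, with -1.22 (-1.52 to -0.93) and -1.42 (-1.91 to -0.96), and the receptor gene Met fell, with -1.57 (-1.71 to -1.42) and -1.36 (-1.63 to -1.09). The lineage list had medians of -0.36, below all 10000 random lists, and 0.14, at percentile 95.3, and 4 of 19 rose and 3 fell, or 5 and 6 adjusted over the list alone.

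Genes of immature and WNT-responsive cells had list medians above 0 in both pairs. Tfap2b, a transcription factor of the neural crest, rose, with 1.40 (1.30 to 1.495) and 1.22 (1.07 to 1.36), and the intermediate filament gene Nes rose, with 1.76 (1.37 to 2.18) and 1.18 (0.52 to 1.85). Cdh19 fell, with -0.55 (-0.84 to -0.26) and -1.04 (-1.24 to -0.84). The neural crest list had medians of 0.19, at percentile 96.3, and 0.43, at percentile 99.9, and 3 of 13 rose and 1 fell, or 5 and 2 adjusted over the list alone. Of WNT targets, Tcf7 rose, with 0.97 (0.72 to 1.22) and 0.86 (0.43 to 1.28), and Nkd2 rose, with 0.98 (0.74 to 1.23) and 0.77 (0.36 to 1.18), while Tcf4 had 0.48 (0.38 to 0.57) and 0.47 (0.36 to 0.57) and did not pass. The list's medians were 0.37 and 0.60, at percentiles 99.97 and 99.99, and 3 of 14 rose and 0 fell, or 6 and 0 adjusted over the list alone. With cells taken by 2 of 5 lineage genes the WNT medians were -0.018 and -0.11 and the recessive neural crest median -0.85, and the recessive ratios turned to -0.98 for Nes, -1.09 for Nkd2 and -0.20 for Tcf4. Among adhesion genes Itga4 fell, with -1.61 (-1.998 to -1.24) and -2.60 (-3.69 to -1.68), as did Ncam1, with -1.53 (-1.72 to -1.35) and -0.76 (-0.98 to -0.54), and Cd44, with -0.50 (-0.59 to -0.41) and -0.70 (-0.86 to -0.54). In all cells outside the melanocyte-like class Cd44 was also lower, with -0.55 and -0.86, so its fall is not particular to melanocyte-like cells. Itga4 had -0.57 and -0.89 there, and Ncam1 -0.44 and -1.31, in cells whose classes differ between libraries. The adhesion list had medians of -0.23, at percentile 0.33, and 0.32, at percentile 99.3 (-0.62 with cells taken by 2 of 5 lineage genes), and 0 of 15 rose and 3 fell, or 3 and 3 adjusted over the list alone.

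**Figure D4:**
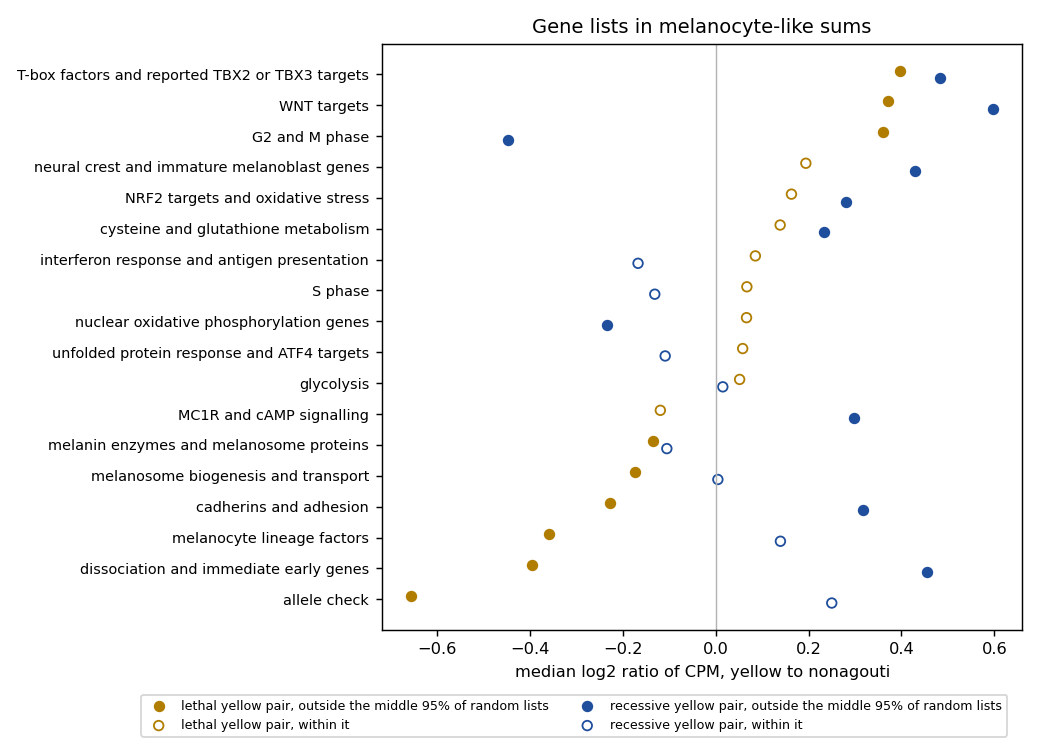
Each point is the median log2 ratio of CPM (yellow to nonagouti) of the measured members of a gene list in 1 pair, over melanocyte-like sums. Filled points lie outside the middle 95% of 10000 random lists matched on mean expression, such as the WNT targets at 0.37 and 0.60, and the G2 and M phase list at 0.36 and -0.45.

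Genes of cell division went opposite ways in the melanocyte-like cells of the 2 pairs. The G2 and M phase list had a median of 0.36 in the lethal pair, above all 10000 random lists, and -0.45 in the recessive pair, below all of them. With cells taken by 2 of 5 lineage genes both turned, to -0.054 and 0.50, and cycling shares were 28.7% and 25.4% in the lethal pair and 57.2% and 37.5% in the recessive pair. By that choice the recessive ratios turned to 0.62 for Ube2c, 0.68 for Cenpa, 0.44 for Ccnb2 and 0.36 for Aurkb. Outside G2 and M phase Ube2c turned to -0.22 in the lethal pair and Cenpa to -0.50 and 1.87. Both genes are on the list by which those cells were chosen, so these turns can come from the choice itself. Ube2c had 0.63 (0.51 to 0.76) and -0.93 (-1.19 to -0.68), Cenpa 0.62 (0.49 to 0.75) and -0.48 (-0.75 to -0.22), Ccnb2 0.34 (0.17 to 0.50) and -0.99 (-1.37 to -0.64) and Aurkb 0.24 (-0.01 to 0.48) and -1.01 (-1.53 to -0.53). After thinning, cycling cells were 22.9% (20.6 to 25.4) of lethal yellow and 15.4% (12.7 to 18.4) of littermate melanocyte-like cells, and 16.8% (10.4 to 25.0) and 20.4% (16.1 to 25.3) in the recessive pair. Without thinning the shares were 44.2%, 43.2%, 46.0% and 53.5%. No G2 and M gene of 25 and no S phase gene of 21 passed the fit, in either direction and also adjusted over the list alone, and the S phase medians were 0.07 and -0.13. The fit tests only what both pairs share. Of the G2 and M genes, 24 of 25 were higher in the lethal pair and 23 of 25 lower in the recessive pair. Their count of 0 thus says nothing of a difference within a pair. In the 5 other classes the lethal medians of the G2 and M phase list ran from -0.0033 to 0.43. Their recessive medians ran from -1.01 to 1.78. Schwann cell-like cells, at 0.24 and -1.01, were split as the melanocyte-like cells were. Fibroblast-like and endothelial-like cells had medians above 0 in both pairs. Calls of cycling cells read free RNA too, so no cycling is read from them alone. Dissociation and immediate early genes also split, with medians of -0.40, below all random lists, and 0.46, above all of them, the latter -0.58 with cells taken by 2 of 5 lineage genes. In the 5 other classes the medians of this list were also below 0, from -0.61 to -0.020 in the lethal pair and from -1.17 to -0.11 in the recessive pair. Junb rose, with 0.43 (0.34 to 0.51) and 1.39 (1.28 to 1.497), the latter -0.25 by 2 of 5 lineage genes, Jun fell, with -0.76 (-0.80 to -0.72) and -0.41 (-0.50 to -0.32), and Klf6 fell, with -0.69 (-0.77 to -0.62) and -0.77 (-0.93 to -0.61). Of 18 genes 1 rose and 2 fell, or 3 and 3 adjusted over the list alone.

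In the remaining lists few genes passed the fit. Xbp1 fell, with -0.64 (-0.81 to -0.46) and -0.80 (-1.15 to -0.46), in an unfolded protein response list with medians of 0.06 and -0.11, of which 0 of 15 rose and 1 fell over all genes and adjusted over the list alone. Irf1 rose, with 0.71 (0.39 to 1.03) and 0.68 (0.33 to 1.03), the latter -0.82 with cells taken by 2 of 5 lineage genes, in an interferon list with medians of 0.09 and -0.17, of which 1 of 13 rose and 0 fell, or 1 and 2 adjusted over the list alone. The recessive median of that list was 0.03 with each cell weighted alike. The lactate dehydrogenase gene Ldha rose, with 0.83 (0.77 to 0.89) and 0.59 (0.51 to 0.68), the latter -0.14 with cells taken by 2 of 5 lineage genes, in a glycolysis list with medians of 0.05 and 0.02, of which 1 of 15 rose and 0 fell, or 2 and 2 adjusted over the list alone. These became -0.04 and -0.05 with each cell weighted alike, and the recessive one -0.03 under TMM scaling. The oxidative phosphorylation list had medians of 0.07, at percentile 30.7, and -0.23, at percentile 0.14 (0.024 with cells taken by 2 of 5 lineage genes), and none of its 17 genes passed in either direction, adjusted over all genes or over the list alone. The X inactivation and Y list had medians of -0.12 and -0.06, and 0 of 4 passed either way, also adjusted over the list alone. Beside all these counts of 0, DESeq2 was run over all genes, with 134 and 150 calls.

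Markers of other cell types stayed low in the melanocyte-like cells. Their median share of a cell's UMIs was 0.0899%, 0.0717%, 0.0919% and 0.0561% in lethal yellow, its littermate, recessive yellow and its control, against 0.839% to 2.52% in the other cells. Schwann cell, neuron and Merkel cell markers were not counted in these shares. Single cells held most UMIs of some markers, such as 162 of 165 of the mast cell gene Cma1 in lethal yellow, 179 of 182 of the macrophage gene Pf4 and 53 of 53 of the muscle gene Myog in the control of recessive yellow, and 43 of 43 of Krt8 and 88 of 162 of the fibroblast gene Dcn in recessive yellow. Among markers that melanocytes can share, Tubb3 rose, with 2.91 (2.57 to 3.26) and 2.33 (1.95 to 2.72), Sparc rose, with 1.15 (1.08 to 1.22) and 1.19 (1.09 to 1.29), turned to -0.071 and -0.90 with cells taken by 2 of 5 lineage genes, and Egfl7 rose, with 0.87 (0.52 to 1.23) and 1.23 (0.73 to 1.73). Cspg4 fell, with -1.32 (-1.63 to -1.03) and -2.12 (-3.07 to -1.29). Lgals7, a keratinocyte gene, had -0.71 (-0.91 to -0.50) and 2.30 (1.999 to 2.60), and Krt17, of the hair follicle, -1.18 (-1.61 to -0.75) and 0.74 (0.05 to 1.42); recessive yellow was also the library with 64.5% hair follicle epithelium-like cells. Without cells rich in other types' markers, Dcn had -0.35 and -0.07 and Krt17 -1.59 in the recessive pair.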

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

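Of the tests in this part, the median of the immediate early list over other classes was chosen only after the result was seen, as were the rule for the 9 genes of the recessive pair, their medians in other classes and the removal of each gene's top cell. The rules for what is listed here were narrowed after the data were seen, to lists and genes on opposite sides in the 2 pairs and to signals picked by hand for agouti and Xist. Differences between the 2 pairs were not tested, since each pair is 1 library against 1.

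The lists of G2 and M phase, dissociation and immediate early, and cadherin and adhesion genes stood out because random lists put their medians on opposite sides in the 2 pairs. The lethal median minus the recessive median was 0.81 for G2 and M phase, -0.85 for the dissociation list and -0.55 for adhesion. With cells taken by 2 of 5 lineage genes the recessive medians of these 3 lists turned, to 0.50, -0.58 and -0.62. For the same reason of opposite 2-fold differences, 6 genes stood out, again as lethal minus recessive log2 ratio. These were Ppargc1a, a coactivator induced by cAMP, at -2.74, 5930430L01Rik at -4.66, Gfod2 at -2.46, the deubiquitinase gene Usp2 at -2.09, Pdzd2 at -2.83 and Gm47283 at 2.57. Agouti stood at 168 CPM in the cells of lethal yellow outside the melanocyte-like class, against 20.3 CPM in the same cells of its littermate, outside the cells compared. Barcodes of at most 100 UMIs held agouti (symbol a) at 137 and 9.14 CPM in these 2 libraries. The lethal yellow cells stood above their barcodes by a log2 of 0.30 (0.19 to 0.42), which free RNA alone does not bring. Xist, expressed from the inactive X chromosome, gave 43 UMIs in 5 of the 113 recessive yellow melanocyte-like cells, against 0 in those of its control. The 1413 other cells of recessive yellow gave 2 Xist UMIs. Y genes were read in all 4 libraries, such as Ddx3y in melanocyte-like cells. It stood at 41.2, 37.2, 63.3 and 63.6 CPM in lethal yellow, its littermate, recessive yellow and its control. Xist in a few cells thus does not show a library of another sex.

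Some immediate early and cAMP-responsive genes were higher in recessive yellow melanocyte-like cells and not 2-fold higher in lethal yellow. Of 18 dissociation and immediate early genes 4 were at least 2-fold higher in this pair, and of 26 MC1R and cAMP genes 8, while others of these lists were lower, such as Klf6 at -0.77 and Pde4b at -2.78. The 9 genes that meet the rule, picked for their size, are Btg2, Crem, Dusp1, Hspa1a, Junb, Nr4a1, Nr4a3, Ppargc1a and Sik1, with a median log2 ratio of 1.53, led by Nr4a3 at 3.48 (3.13 to 3.84) and Sik1 at 2.85 (2.38 to 3.34). Stress of the whole library at dissociation argues for higher levels in other cells too, yet the list's median over 5 other classes was -0.74, with classes from -1.17 to -0.11. The -1.17 is that of hair follicle epithelium-like cells, which were mostly of cluster 3 in recessive yellow and of cluster 1 in its control, and the other 4 classes lay from -0.74 to -0.11. Of the 9 genes themselves, 7 or 8 were measured in each of those 4 classes, with medians from -0.89 to 0.17. A single cell per gene is not the whole source either, since the median was 1.49 without each gene's top cell, while several rich cells among the 113 stay open. A stress specific to these melanocytes, and a difference of the genotype that lethal yellow does not share, both stay open and untested with 1 library of 113 cells.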

How the results depend on the processing

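Of the tests in this part, leaving out cells rich in other types' markers and leaving out each gene's top cell were chosen only after the result was seen, as were the median over the 10 named genes of a pair and the share of cells with 2 of 5 lineage genes. Cell numbers stayed within 1.5 times and melanocyte-like shares within their intervals under the alternatives of filters, matrix and clustering. Taken by 2 of 5 lineage genes in place of clusters, the cells were 43.7%, 34.9%, 24.6% and 23.9% of lethal yellow, its littermate, recessive yellow and its control. The lower share of the recessive pair did not stay by that choice, which took many cells outside the melanocyte-like class. The alternative minimum of 2000 UMIs was looser than the minimums used, which ran from 3195 to 6960, and barcodes between them were not scored for doublets. Of 2960 values of named genes under alternatives, 2574 stayed within their counting interval, 340 left it and 46 turned direction. Of 492 list medians these counts were 410, 69 and 13. A turn was counted only for genes whose interval left out 0 and for lists outside the middle 95% of random lists, and further list medians changed sign without being counted as turned. Of 203 other values 137 stayed and 66 moved. No ratio is given where an alternative left at most 3 counts on both sides. Recessive yellow gave the smallest sum, 2415981 UMIs over 113 melanocyte-like cells, and this depth limits the intervals of its pair. The cause was not tested for any value below unless it is stated.

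The fit called 343 genes higher and 366 lower. Without the pair block, the "no replicate block" fit called 0 and 0 with edgeR (276 and 277 at an unadjusted p under 0.05, and 56 and 66 with DESeq2), since the difference between the pairs then counts as error. DESeq2 with the block called 134 and 150, a mitochondrial limit of 20% gave 209 and 228, and no filter gave 558 higher. Under the 20% limit the melanocyte-like cells numbered 1219, 647, 113 and 326, against 1216, 643, 113 and 318 before. The number of genes called thus moved with a change of few cells. The other alternatives run on this fit stayed within 1.5 times, from 245 to 469 higher and from 268 to 506 lower. TMM scaling moved the median of all genes by 0.06 and -0.05.

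Taking cells by UMIs of at least 2 of 5 lineage genes from any cluster changed most results, which follows from the cells it takes, since 1210 of 1535, 642 of 885, 112 of 376 and 316 of 571 were melanocyte-like. The fit then called 0 higher and 1 lower with edgeR (256 and 727 at an unadjusted p under 0.05, and 23 and 111 with DESeq2). In both pairs 32 genes were higher, 40 went in opposite directions, r was 0.27 and rho 0.13. The medians of the 10 named genes were 3.75 and -3.80 in the lethal yellow pair and 1.73 and -5.04 in the recessive yellow pair. Cycling shares were 28.7%, 25.4%, 57.2% and 37.5% in lethal yellow, its littermate, recessive yellow and its control. In the lethal pair the medians of WNT targets and of G2 and M phase turned to -0.018 and -0.054. In the recessive pair the medians turned to -0.15 for MC1R and cAMP signalling, -0.39 for T-box factors and reported TBX2 or TBX3 targets, -0.85 for neural crest and immature melanoblast genes, -0.11 for WNT targets, -0.62 for cadherins and adhesion, -0.047 for NRF2 targets and oxidative stress, 0.50 for G2 and M phase, -0.58 for dissociation and immediate early genes and 0.024 for nuclear oxidative phosphorylation genes. Of the named genes in the lethal pair, Cox7a2 turned to 0.0029, Dcn to -0.67, Fabp4 to 0.41, Itga6 to -0.062 and Sparc to -0.071. In the recessive pair log2 ratios turned positive for Aurkb (0.36), Ccnb2 (0.44), Cenpa (0.68), Ctss (0.17), Lama3 (0.18), Mcm5 (0.051), Ube2c (0.62) and Uqcrc1 (0.30). Those that turned negative included Cdh1 (-0.40), Fth1 (-0.21), Gstm1 (-0.22), Hspa5 (-0.30), Ier3 (-0.56), Irf1 (-0.82), Itga6 (-0.32), Junb (-0.25), Ldha (-0.14), Luzp2 (-1.16), Mlana (-0.039), Mlph (-0.63), Nes (-0.98), Nkd2 (-1.09), Prss23 (-0.36), Rab38 (-0.42), Sparc (-0.90) and Tcf4 (-0.20).

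In cells outside G2 and M phase, 60 genes were higher and 82 lower in both pairs, with r at 0.55 and rho at 0.33 and fewer genes measured, and the median of the genes named higher in the lethal yellow pair was 4.25. The allele check median of the lethal pair turned to 0.59. Calr turned to 0.21, Cenpa to -0.50, Dcn to -0.028, Fabp4 to 0.057 and Ube2c to -0.22 in the lethal pair, and Cenpa to 1.87, Dcn to -0.33, Lef1 to -0.049 and Prdx6 to -0.022 in the recessive pair. Cenpa and Ube2c are on the list that chose these cells, so their turns can come from the choice itself. A minimum of 20 UMIs gave 24 genes in opposite directions and r of 0.55. A minimum of 200 gave 43 higher, 62 lower and 1 opposite, rho of 0.39, medians of 4.14 and -5.11 for the recessive yellow pair, and 0.54 for the allele check in the lethal pair, where fewer of its genes were left.

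With each cell weighted alike, r was 0.57, rho 0.33 and the median of the genes named higher in the recessive yellow pair 4.44. A pseudocount of 1 CPM pulled ratios toward 0 by construction, to medians of 3.33 and -3.89 in the lethal yellow pair and 4.05 higher in the recessive yellow pair, with 3 opposite genes and r of 0.59. With predicted doublets kept, the recessive yellow pair's higher median was 4.11, r 0.59 and rho 0.37, and Dcn turned to -0.12 in it. The second matrices gave r of 0.59. Without cells rich in other types' markers the recessive yellow pair's lower median was -5.04 and rho 0.36, and Dcn turned to -0.35 and -0.067 in the lethal and recessive pairs and Krt17 to -1.59 in the recessive one. Without each gene's top cell the recessive yellow pair's medians were 4.52 and -5.11, 2 genes were opposite, and Dcn turned to -0.11 and Fabp4 to 0.082 in the lethal pair.

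Shares of cycling cells with at least 1 gene were 42.3%, 34.99%, 35.4% and 37.4% in lethal yellow, its littermate, recessive yellow and its control. With at least 3 genes they were 17.2%, 11.8%, 13.3% and 15.7%, and without thinning the shares were 44.2%, 43.2%, 46.0% and 53.5%.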

Other observations

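Of the tests in this part, the correlation in other classes, the recount over the same genes and the comparison with low-UMI barcodes were chosen only after the result was seen, as was the removal of cells rich in other types' markers. The rule for genes that differed in all classes was set after the files had been looked at, and a looser form was tried and not kept.

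Some genes differed at least 2-fold in the same direction in every measured class of a pair, in 4 classes or more. In the lethal pair these were agouti, higher in 6 classes with a median log2 ratio of 7.66, the neuropeptide gene Npy, higher in 4 classes with 2.94, and the class I histocompatibility gene H2-T23, lower in 4 classes with -1.35. In the recessive pair Eif3j2 was higher in 5 classes with 4.08, Wdfy1 in 6 with 1.62 and C77080 in 5 with 1.26, and Pusl1 was lower in 4 with -2.30. Npy was among the leading genes of the melanocyte-like clusters, at 2130 against 441 CPM in melanocyte-like cells of the lethal pair. In the other cells of lethal yellow it stood at 40.1 CPM, against 672 CPM in barcodes of at most 100 UMIs. In those of its littermate it stood at 8.27 against 103 CPM. Both levels lie far below the barcodes, so free RNA of melanocyte-like cells is not excluded as the whole source of Npy in the other classes. Agouti (symbol a) stood at 168 CPM in the lethal yellow cells outside the melanocyte-like class, above its 137 CPM in barcodes of at most 100 UMIs, while the melanocyte gene Pmel stood at 59.7 against 727 CPM. Free RNA is thus not the whole source of agouti in these cells as a whole.

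The 259 genes that differed 2-fold in the same direction in both pairs were weighed against 4 technical explanations. A difference in handling or library that reaches all cells would show in other classes, but the highest correlation of the pairs among 5 other classes was 0.154, against 0.60. The 0.154 is that of hair follicle epithelium-like cells, mostly of cluster 3 in recessive yellow and of cluster 1 in its control, and the highest of the other 4 was 0.123. The share of cells in G2 and M phase was tested in cells outside these phases by their unthinned UMIs. There 142 genes were counted, between the bounds set beforehand, 130 and 173, so this count did not decide. Over the same 259 genes 210 stayed at 2-fold, although only 149 kept the count minimum, which argues against phase as the whole cause. With cells taken by 2 of 5 lineage genes only 99 of the 259 stayed at 2-fold. Without cells rich in other types' markers 260 genes were counted, and 246 of the 259 stayed at 2-fold. This argues against doublets with the cell types whose markers were counted. Markers of Schwann cells, neurons and Merkel cells were not counted, so doublets with these types stay open. That filter left out only 32, 10, 4 and 5 cells and leaves free RNA in place. Free RNA cannot bring a gene above its own level in barcodes of at most 100 UMIs, and 168 of the 259 genes stood above that level on their higher side in both pairs. Against bounds of 130 and 173, set first, this share did not decide, and the genes were then read in 2 parts. For the 168 genes free RNA is not the whole source, and for the other 91 it stays open. A shared effect of low MC1R signalling, and a gate that took different melanocytes in yellow and black skin, stay open too and were not tested.

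The 4 genes that differed in all classes of the recessive pair were weighed against 2 explanations. Reads shared between near-identical copies are a candidate explanation for Eif3j2, which had 2227 against 126 UMIs over all cells while its copy Eif3j1 had 4515 against 6673, and their sum had a log2 ratio of 0.10. This covers 1 of the 4 genes, since the others have no named copy. A stretch of another strain's genome next to Mc1r, on chromosome 8, would place them there, but 0 of the 4 genes lie on that chromosome. Strain differences elsewhere and differences between the animals stay open for Wdfy1, C77080 and Pusl1, of which C77080 and Pusl1 both lie on chromosome 4 and Wdfy1 on chromosome 1.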
